A study of Caenorhabditis elegans with 7 samples.

How the data were processed

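Total RNA from adult Caenorhabditis elegans of strain CF512 was hybridised to 7 two-colour spotted arrays, each against a common reference RNA named HS1. Per the labels, the animals were grown at 25 °C, a temperature at which this strain is sterile, and then moved to 30 °C. The arrays stand for 0, 2, 4, 6, 8, 10 and 12 h at 30 °C, with 1 array per time point.

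The deposited table holds 1 log2 ratio per probe and array. Log base 2 is taken from the range of the values and is not stated in the sources used here, so fold changes hold only if the base is 2. The deposited column means lie near 0, so each array may have been centred before deposit. The deposited values stop at exactly -5 and 5, and 65 of the 19200 probes reach such a limit on at least 1 array. The scanner, background correction, normalization and the filter behind blank cells are not given in the sources used here. The direction of the ratio is not stated either. Spot intensities were not analysed here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

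Between 11.6% (0 h) and 15.9% (12 h) of the probes had no value on an array, 942 probes had none on any array, and 13552 had one on all 7. The platform annotation pairs 7900 probes with 1 gene, none with several, and leaves 11300 unnamed here. Of the gene rows, 7872 matched the WBcel235 reference gene table by gene number and took their current names from it, and 28 kept the name of the annotation. That table was used only for names, gene types and gene order, because the build behind the probes is not given in the sources used here. The 7900 probes name 7534 genes, of which 316 are on several probes and were averaged. Unnamed probes stayed features of their own.

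Each array was centred on its median. The deposited column medians before this lay between -0.02 (0 h) and 0.06 (10 and 12 h). Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were a linear trend over 0 to 12 h on all 7 arrays, the mean of the 6 heated arrays against the baseline array, and a linear trend over 2 to 12 h on the heated arrays. Trends are given as the fitted change over the whole span. With the 0 h array left out, the trend over 0 to 12 h becomes the fit over 2 to 12 h. Its slope is then scaled to 12 h. Features had to be measured on every array of a comparison. No time point has a replicate, so the error is the spread of single arrays about the fitted line or about the heated mean, and the baseline array is assumed to vary like the others. The difference between the 2 h and 0 h arrays was computed with no test.

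Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Lists with fewer than 4 measured genes received values only. Of 27 lists chosen before the data were examined, 19 had no gene on a named probe, because most named probes carry genes known by their sequence name, and 3 could be tested. A further 18 lists were put together from the gene names on the array, before gene values were looked at, and all were testable. Random lists numbered 10000.

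Genes named in the text follow a rule set before the data were examined. It takes the 8 highest and 8 lowest fitted changes past the threshold for the trend over 0 to 12 h and for heated against baseline. For the other trend and for the 2 h difference it takes the 5 highest and 5 lowest. The rule also names up to 4 members per list and 14 heat shock and stress genes. Of these 14, only F44E5.4 had a named probe, and whether unnamed probes carry the others is unknown here. Genes outside the rule are said to be chosen after their values were seen.

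The fits were tested on simulated data with the real residual spread and errors independent between arrays. In each simulation 100 features were changed by 1 log2 unit and another 100 by 2. For a change of 1 log2 unit, 7 of 100 were recovered in the trend over 0 to 12 h, 6 in heated against baseline and 5 in the trend over 2 to 12 h. For a change of 2 log2 units the numbers were 56, 51 and 63. Of the unchanged features, 3, 4 and 6 were called. Alternatives included no centring, quantile normalization, scaling to equal median absolute deviation, tolerance of missing values, single probes, a robust variance prior, other time scales and leaving out each array. Centring within the 32 print blocks and setting values at the limits to missing were added after seeing the data.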

Results

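The transcriptional response of sterile adult worms to a shift from 25 °C to 30 °C was followed on 7 arrays, with 1 array at each of 0, 2, 4, 6, 8, 10 and 12 h. Each value is taken as a log2 ratio of worm RNA to a common reference, so it gives no absolute level. Each time point has 1 array, and no value has a replicate error of its own. Between 16143 and 16972 probes had a value on an array. The standard deviation over probes was 0.634 at 0 h and between 0.497 (4 h) and 0.585 (12 h) on the heated arrays. The correlation over probes between the 0 h array and a heated array went from 0.234 at 2 h to -0.212 at 12 h, and probes are not independent replicates.

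The direction of the deposited ratios is not stated. F44E5.4 and F44E5.5, adjacent and near-identical genes for heat-inducible HSP70 chaperones, had their lowest ratio at 0 h, where both stood at the lower limit of the file (-4.98 after centring). Their ratios were 0.91 and 0.83 at 2 h and 1.64 and 1.29 at 4 h. On this basis the likely direction is worm RNA over reference, and it is used throughout. With the sign turned, every count of higher and lower features below changes places.

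The first question was which transcripts differed, on the mean of the 6 heated arrays, from the unheated baseline. A change at a single time can be missed this way. The HSP70 gene F44E5.4 rose by at least 5.26 log2 units (SE 0.87, n = 6 heated arrays against 1; limma adjusted p = 0.0254), and F44E5.5 rose by at least 5.25 (SE 0.67; limma adjusted p = 0.00914). The direction of the ratio was chosen from these 2 genes, so that they rose is an assumption, and the p-values bear only on the size of the difference. Both are lower bounds, since the baseline stood at the limit of the file, and both correspond to about 38-fold or more if the logs are of base 2. The neighbouring copies cannot be separated without the probe sequences. The pseudogene Y38H6C.7 rose by 5.16 (SE 0.41), ZK816.3 by 5.03 (SE 0.97), F57A8.1 by 4.90 (SE 0.50), C23G10.1 by 4.86 (SE 0.40), the pseudogene C01G10.13 by 4.36 (SE 0.54) and Y46H3A.4 by 4.22 (SE 0.39), each above the baseline on 6 of 6 heated arrays. In the WBcel235 gene order, Y46H3A.4 lies near the small heat shock genes hsp-16.2 and hsp-16.41, with srt-42 between. Among named genes past the threshold, the lowest changes were those of T16G1.7 (-4.04, SE 0.68) and ltah-1.2 (-3.92, SE 0.78), then F25D1.5 (-3.70), C46H11.2 (-3.26), F28H7.3 (-3.22), T16G1.6 (-3.05), ZK669.2 (-2.999) and T03E6.8 (-2.98), all below the baseline on every heated array. T16G1.6 and T16G1.7 are adjacent genes.

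Of 13369 features tested with limma, 219 passed the threshold, 91 higher and 128 lower, and 37 and 53 of these were named genes. At an unadjusted p under 0.05 there were 2347. The baseline is 1 array, so anything particular to it counts here as an effect of heating, and the spread comes only from the 6 heated arrays, which stand for different times. Of the 219, 10 had their baseline at a limit of the file. The 8 to 12 h arrays alone against the baseline gave 429 features and the 2 to 6 h arrays alone gave 93. Quantile normalization gave 88 features, 53.4% of them higher against 41.6% here, and scaling to equal median absolute deviation gave 44 higher and 60 lower. Without the 2 h array there were 431, without the 6 h array 115 and without the 8 h array 110. F44E5.4, F25D1.5, F28H7.3, T03E6.8, T16G1.6, T16G1.7, ZK816.3 and ltah-1.2 lost their call in at least 1 alternative. Of 15 alternatives, ZK816.3 kept its call in 6, T03E6.8 in 7 and ltah-1.2 in 8. The others named here kept theirs in 10 or more.

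**Figure D1:**
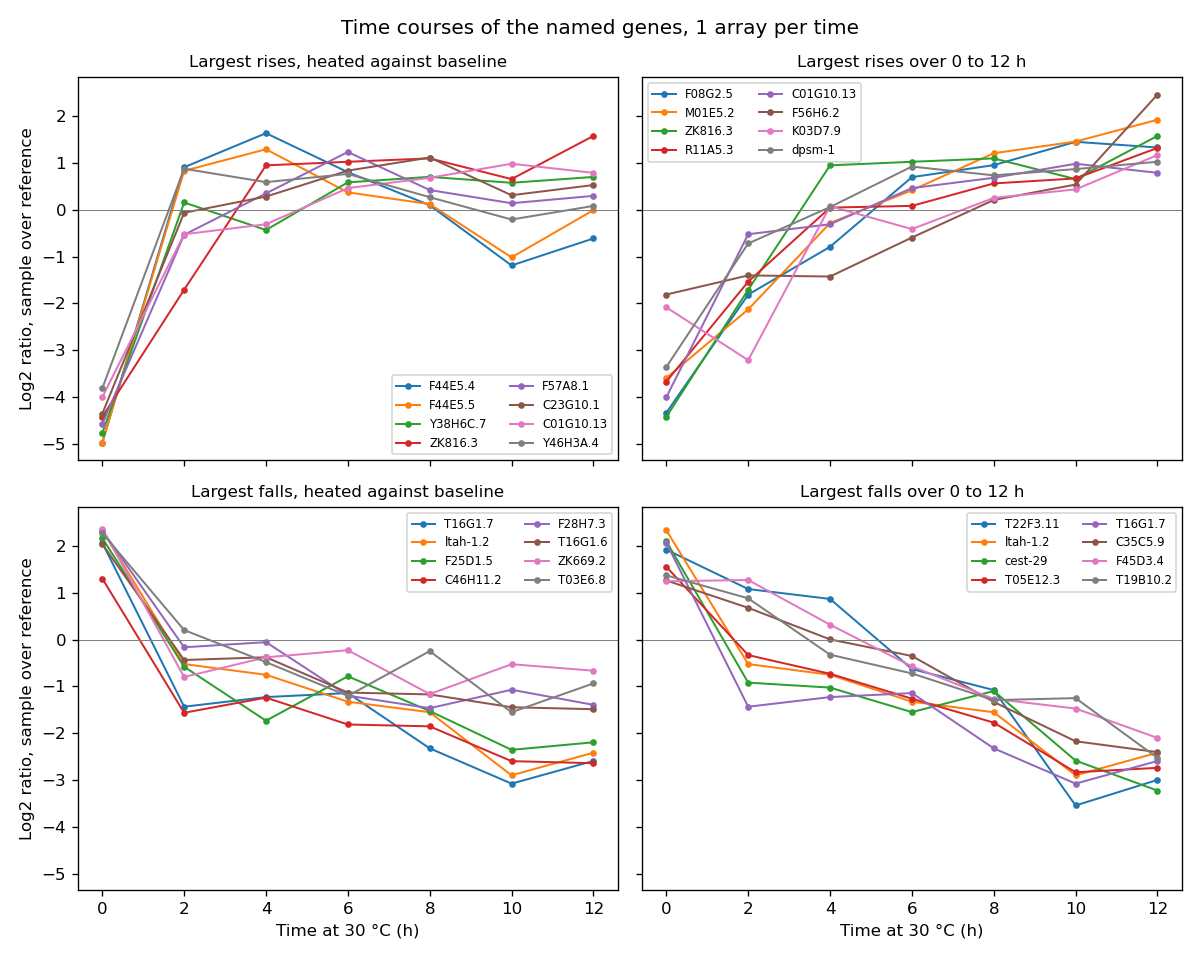
Log2 ratio of worm RNA to reference (vertical axis, median-centred, 1 array per time) against hours at 30 °C (horizontal axis) for the genes with the largest fitted changes past the threshold. F44E5.4 and F44E5.5 stood highest at 4 h (1.64 and 1.29), while F56H6.2 and M01E5.2 stood highest at 12 h (2.46 and 1.93).

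The next question was which transcripts had a linear trend over the whole course. A shift between 0 and 2 h can also give such a trend, so a call does not mean a steady change. F08G2.5 rose by 5.42 log2 units over 12 h (SE 0.80, 7 arrays; limma adjusted p = 0.009), and M01E5.2 rose by 5.41 (SE 0.58; limma adjusted p = 0.00295). ZK816.3 rose by 4.91, R11A5.3 by 4.27, the pseudogene C01G10.13 by 3.94, F56H6.2 by 3.93, the pseudogene K03D7.9 by 3.70 and dpsm-1 by 3.65. T22F3.11 fell by 5.57 (SE 0.56; limma adjusted p = 0.00228), from a ratio of 1.93 at 0 h to -2.998 at 12 h. ltah-1.2 (-4.25), the carboxylesterase-family pseudogene cest-29 (-4.16), T05E12.3 (-4.06), T16G1.7 (-3.94), C35C5.9 (-3.87, SE 0.26), F45D3.4 (-3.67) and T19B10.2 (-3.63) fell too. Some of these genes changed mostly in the first interval, with a difference between 2 h and 0 h of -3.51 for T16G1.7 and 3.49 for C01G10.13. In contrast, F44E5.4 had a fitted change of 1.58 (SE 1.96, limma adjusted p = 0.686) and F44E5.5 one of 2.15 (SE 1.81, limma adjusted p = 0.528), since their ratios stood highest at 4 h and lay at -1.19 and -1.02 at 10 h. With the 0 h value at the limit of the file these are not exact changes, and without the 0 h array their signs turned, to -2.88 and -1.95.

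In this trend 715 of 13369 features passed the threshold with limma, 230 higher and 485 lower, and 101 and 180 of these were named genes. Among the 91 features higher with heating, the highest ratio fell at 2 h for 12, at 4 h for 20, at 6 h for 15, at 8 h for 15, at 10 h for 16 and at 12 h for 13. The trend count was 156 without the 0 h array (128 of them shared with the 715), 354 without 2 h, 457 without 8 h, 284 without 10 h and 385 without 12 h. It was 414 with quantile normalization and 1101 with time on a log scale. ZK816.3, C01G10.13, K03D7.9, dpsm-1, cest-29 and T16G1.7 lost their call in at least 1 alternative, with limma adjusted p up to 0.229 (ZK816.3). Of 15 alternatives, ZK816.3, C01G10.13 and T16G1.7 kept it in 6 each, K03D7.9 and dpsm-1 in 9 each and cest-29 in 12. F08G2.5, M01E5.2, R11A5.3, F56H6.2, T22F3.11, ltah-1.2, T05E12.3, C35C5.9, F45D3.4 and T19B10.2 kept theirs in every alternative. Without the 0 h array the fitted change over 12 h was 2.68 for ZK816.3, 1.83 for C01G10.13, 1.88 for dpsm-1, -2.15 for T16G1.7, -2.77 for ltah-1.2 and -2.70 for cest-29. These are slopes of the 2 to 12 h fit below, extended to 12 h. The 156 features without the 0 h array are those of that comparison, not a separate result.

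Change within the heating period was asked of the 2 to 12 h arrays alone. M01E5.2 rose by 3.76 log2 units over these 10 h (SE 0.48, n = 6 arrays; limma adjusted p = 0.0184), F56H6.2 by 3.72, F08G2.5 by 3.25, F19B10.6 by 3.04 and T27C5.10 by 3.03. T22F3.11 fell by 4.87 (SE 0.60; limma adjusted p = 0.0179), as did F45D3.4 (-3.28), C35C5.9 (-3.28), E01A2.8 (-3.25) and F23H12.5 (-2.96). F19B10.6 had a ratio of -0.10 at 0 h and -2.79 at 2 h, and returned to 0.54 by 12 h. Of 13478 features, 156 passed with limma, 51 higher and 105 lower, including 28 and 44 named genes. At an unadjusted p under 0.05 there were 1971. All these calls were lost without the 2 h array, where limma called 0 features and 1309 had an unadjusted p under 0.05. The count was 16 without 12 h, 42 without 10 h, 77 without 8 h, 87 without 6 h and 91 without 4 h. It was 63 with up to 2 missing arrays allowed and 101 with quantile normalization, where 43.6% were higher against 32.7% here.

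The first interval rests on 1 array at each end and has no test. F44E5.4 was at least 5.89 log2 units higher at 2 h than at 0 h and F44E5.5 at least 5.82, both with the 0 h value at the limit of the file. F19B2.5 was higher by 5.16, Y38H6C.7 by 4.93 and Y46H3A.4 by 4.70. Among named genes the lowest differences were those of F59D12.3 (-4.26), Y62H9A.2 (-4.21 or lower, with the 2 h value at the limit of the file), F40G12.3 (-3.67), the acyl-CoA oxidase gene acox-3 (-3.53) and T16G1.7 (-3.51). F59D12.3 had no value at 4, 8, 10 and 12 h, and stood at 0.16 at 0 h and 1.11 at 6 h. F40G12.3 had none at 4 h, and stood at 0.02 at 0 h and -0.02 at 6 h. For both, the low ratio was thus seen on the 2 h array alone. Y62H9A.2 had no value at 4, 6 and 12 h. F19B2.5 stood at 1.41 at 2 h and -1.09 at 12 h. Over 15461 features, 589 were higher by 1 log2 unit or more and 1064 lower.

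Among the gene groups, 5 of 23 measured carboxylesterase-family genes fell over 0 to 12 h, 0 rose and 18 did not pass. Adjusted over the list alone, 12 fell. The median change of the family was -1.01, with camera adjusted p = 5.93e-05, and adjusted p = 0.404 with an estimated correlation. The family list was put together from the gene names on the array. cest-29, cest-1.2 (-2.997, SE 0.70), cest-17 (-1.84, SE 0.35), cest-9.1 (-1.82, SE 0.34) and cest-8 (-1.53, SE 0.37) were the members that fell. Each of these 5 calls was lost without the 0 h array, with limma adjusted p from 0.0656 (cest-29) to 0.249 (cest-1.2). The fitted changes over 12 h were then -2.70 for cest-29, -2.13 for cest-1.2, -1.53 for cest-17, -1.31 for cest-9.1 and -1.53 for cest-8. Against the baseline the family median was -0.89 and 1 member fell, cest-27 (-1.65, limma adjusted p up to 0.113 in the alternatives), with camera adjusted p = 0.000131, and adjusted p = 0.363 with an estimated correlation. Within 2 to 12 h, which is the fit without the 0 h array on its own span, the median was -0.49 and 0 members passed. Camera gave adjusted p = 0.00664, adjusted p = 0.345 with an estimated correlation, and adjusted p = 0.176 without the 12 h array.

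**Figure D2:**
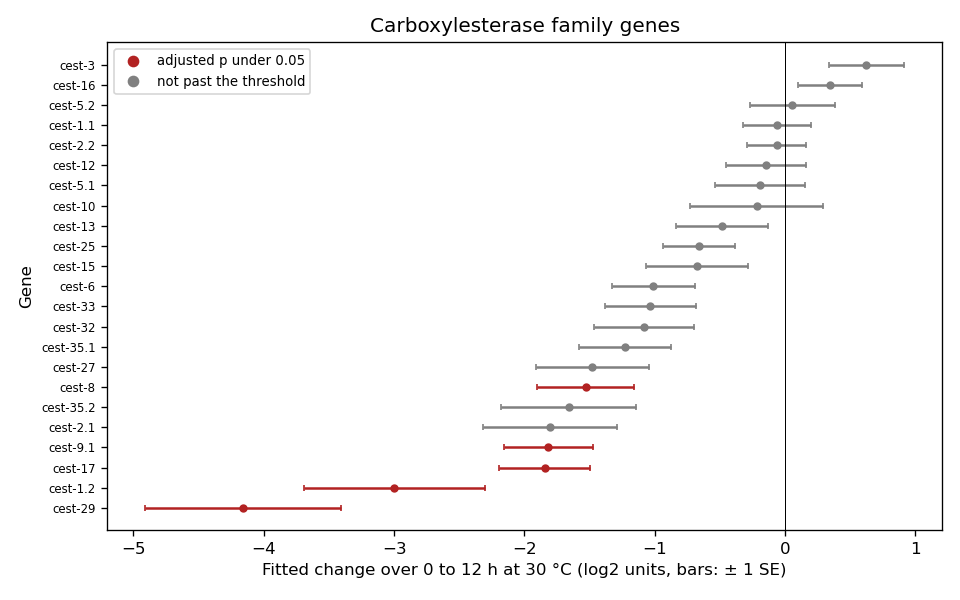
Fitted change over 0 to 12 h at 30 °C (horizontal axis, log2 units, points with bars of 1 standard error, 7 arrays) of the 23 measured carboxylesterase-family genes (vertical axis). The 5 genes past the threshold lie between -4.16 (cest-29) and -1.53 (cest-8), and 3 members have a change above 0.

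Nucleolar ribosome assembly factors had a median of 0.33 against the baseline over 19 measured genes, 16 of them above 0 and 0 past the threshold singly, with camera adjusted p = 0.019 and adjusted p = 0.363 with an estimated correlation. Examples were utp-11 (0.87), shq-1 (0.79), rrp-1 (0.79) and nol-56 (0.71). Over 0 to 12 h their median was 0.35, with camera adjusted p = 0.073. It was 0.25 without the 0 h array (camera adjusted p = 0.581). Translation factors had a median of 0.53 over 0 to 12 h for 8 measured genes, with camera adjusted p = 0.092. None of them passed, and 1, eif-2gamma (0.98), passed adjusted over the list alone. Of the respiratory chain and ATP synthase list, 5 genes were measured on all arrays, all of the respiratory chain. Its ATP synthase gene, atp-1, was not measured on all arrays. The median of the 5 was 0.07, and 0 passed, also when adjusted over the list alone. The F-box, SKP1-related and PALS list had 19 measured genes, of which 18 were PALS genes, and it held no SKP1-related gene. Of the 19, 1 rose, pals-26 (2.59, SE 0.46), also when adjusted over the list alone, and the median was 0.04. pals-26 had a change of 2.19 without the 0 h array (limma adjusted p = 0.115), and it passed neither there nor against the baseline.

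Of the 11 measured genes of fatty acid oxidation, 2 fell against the baseline and 9 did not pass. These were acox-1.6 (-2.76, SE 0.27) and acox-1.4 (-2.38, SE 0.47), both genes for acyl-CoA oxidases, with a list median of -0.23 (camera adjusted p = 0.175, and 0.394 with an estimated correlation). acox-1.4 lost its call in some alternatives (limma adjusted p up to 0.148). Of 13 proteostasis genes, F44E5.4 and F44E5.5 rose and lonp-2, for a peroxisomal Lon protease, fell by 2.30 (SE 0.42; limma adjusted p up to 0.116 in the alternatives), with a list median of 0.31 (camera adjusted p = 0.103). psme-4, for a proteasome activator, rose by 1.45 over 0 to 12 h (SE 0.23). Its change was 1.32 without the 0 h array (limma adjusted p = 0.0708), and it passed neither there nor against the baseline. Of 21 solute carriers, 2 fell over 0 to 12 h, slcr-46.1 (-2.19, SE 0.44) and mfsd-8.5 (-1.71, SE 0.30), and the list median was -0.20 (camera adjusted p = 0.151). Neither passed without the 0 h array (limma adjusted p = 0.161 and 0.101) or against the baseline (0.143 and 0.0994).

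The other lists gave no call with camera in any of the 3 fitted comparisons. They were PALS proteins, signal peptidase and secretory pathway, N-glycosylation and GPI anchor synthesis, splicing factors, respiratory chain with assembly factors, DNA replication and cohesion, germline small RNA, sperm-associated, eggshell and uterine lumen, neuropeptides and receptors, zinc and heme transporters, GTNT and NSSP proteins. Fry asks whether the genes of a list move on balance one way and does not compare them with other genes. Over 0 to 12 h the lists past the threshold with fry were solute carriers (adjusted p = 0.0119), translation factors (0.0136) and carboxylesterases (0.0210). Against the baseline they were proteostasis, DNA replication and fatty acid oxidation (0.0349 each), and nucleolar factors and carboxylesterases (0.0485 each). Over 2 to 12 h they were carboxylesterases and solute carriers (0.0230 each). The proteostasis list holds F44E5.4 and F44E5.5, which cannot be separated without the probe sequences. Its mean against the baseline was 0.85 and its median 0.31, with 11 of 13 changes above 0. Fry was not run without this pair. No list passed in camera with an estimated correlation, where the lowest adjusted p was 0.345. Mean and median, or the direction of the test, differed in sign for the secretory, N-glycosylation and sperm-associated lists over 0 to 12 h, for the sperm-associated, transporter, solute carrier and GTNT lists against the baseline, and for the proteostasis, DNA replication, sperm-associated, GTNT and NSSP lists over 2 to 12 h. Lists with fewer than 4 genes gave values only. ugt-66, for a UDP-glucuronosyltransferase, fell by 1.86 over 0 to 12 h (SE 0.35), but passed neither without the 0 h array (limma adjusted p = 0.125) nor against the baseline (0.168), while lonp-1 had a change of 0.91, timm-17B.1 -0.10 and the ribosomal gene rpl-37.1 -0.15. spp-24 and ugt-67 were not measured on all arrays. In the difference between the 2 h and 0 h arrays, the carboxylesterase median was -0.63, below all 10000 random lists. That of nucleolar factors was 0.35 (percentile 99.6). That of the F-box, SKP1-related and PALS list was -0.31 (percentile 0.97), with 23 of its 24 measured genes PALS genes. These values are a description of these arrays.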

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

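Centring within print blocks and setting values at the limits to missing were chosen after seeing the data. No paired analysis was possible because each time point has 1 array. The baseline array cannot be left out of heated against baseline. The cause of each shift below was not tested, except that fewer arrays or more features enter some fits. Counts are given as features higher and lower. For the trend over 0 to 12 h, 230 and 485 became 154 and 260 with quantile normalization, 144 and 338 with equal median absolute deviations, 151 and 393 with up to 2 missing arrays, and 394 and 707 with time as log2 of hours plus 1. A test of linear and quadratic terms together called 707 against 715, of which 474 were shared with the straight line, and 0 passed in the quadratic term alone. Leaving out each array gave 51 to 188 higher and 105 to 426 lower. For heated against baseline, 91 and 128 became 47 and 41 with quantile normalization, 44 and 60 with equal median absolute deviations, 45 and 48 with 2 to 6 h only, and 140 and 289 with 8 to 12 h only. Leaving out each heated array gave 46 to 158 higher and 64 to 273 lower. For the trend over 2 to 12 h, 51 and 105 became 44 and 57 with quantile normalization and 20 and 43 with up to 2 missing arrays, and leaving out each array gave 0 to 38 higher and 0 to 59 lower. Lists past the threshold numbered 1, 2 and 1 in these comparisons. With an estimated correlation they numbered 0, 0 and 0, and with print block centring 2 over 0 to 12 h and 2 over 2 to 12 h. Leaving out arrays gave 1 to 2, 2 to 2 and 0 to 1. The carboxylesterase median over 0 to 12 h, -1.01, was -0.59 without the 0 h array, and that over 2 to 12 h, -0.49, was -0.29 without the 12 h array. The -0.59 and the -0.49 come from the same fit, scaled to different spans. With the sign of all values turned, the change of F44E5.4 was -5.26. The fitted trend over 0 to 12 h of F44E5.4, 1.58, went from -2.88 without 0 h to 2.72 without 2 h, and that of F44E5.5, 2.15, from -1.95 to 3.37, and neither passed in any of these. Without centring, the median change of all features was 0.098 for the trend over 0 to 12 h and 0.108 for heated against baseline. The counts of the first interval stayed within 1.5 times. The signal over background behind each ratio was not analysed here, so how weak spots limit the values is unknown.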

Other observations

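Of the tests in this part, the baseline test and those of print block offsets and cross-hybridisation for the carboxylesterases were chosen after the result was seen. The genes in this paragraph and the next were chosen after their values were seen, so no test of them as sets is given. Purine metabolism genes included pnp-1, for purine nucleoside phosphorylase, which fell by 2.84 over 0 to 12 h (SE 0.31), pfas-1, of purine synthesis, which fell by 2.60 (SE 0.42) but did not pass without the 0 h array (limma adjusted p = 0.0524), and gda-1, for guanine deaminase, which fell by 2.18 (SE 0.30). xdh-1, for xanthine dehydrogenase, fell by 1.76 over 2 to 12 h (SE 0.29), but did not pass over 0 to 12 h (-1.37, limma adjusted p = 0.0960) and was 1.06 higher at 2 h than at 0 h. Its call over 2 to 12 h was lost in some alternatives (limma adjusted p up to 0.256). Of the other members looked at, adk-1 had a change of 0.46 over 0 to 12 h, aprt-1 -0.59, gda-2 -0.19 and gmpr-1 -0.36, and none of these passed. Against the baseline, hphd-1, for a hydroxyacid-oxoacid transhydrogenase, fell by 2.88 (SE 0.27).

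The hsp-16 genes had no named probe, but genes beside them did. In the WBcel235 gene order, 6 measured genes lie within 3 genes of an hsp-16 gene. Higher with heating were Y46H3A.4, Y46H3A.5 (2.14, SE 0.30), T27E4.1 (2.48, SE 0.34), F21C10.10 (3.01, SE 0.59) and F21C10.9 (1.24, SE 0.21), while T27E4.7 had a change of -1.61 and did not pass. Of 15 alternatives, T27E4.1 kept its call in 14, F21C10.9 in 7 and F21C10.10 in 6. Y46H3A.4 and Y46H3A.5 lie together, and the others lie together at another locus, so these genes are not separate instances. Among all 5315 named genes tested, 37 were higher with heating.

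The order of the arrays was tested by drawing 100 orders of the times, the real one included. For the trend over 0 to 12 h the real order called 715 features and the highest other order 4. Thus 1 of 100 called as many, which argues against a chance order of the times. For the trend over 2 to 12 h the real order called 156 and the highest other 20, again 1 of 100. That trend called 0 features without the 2 h array. With 1 array per time, chance differences between single arrays cannot be excluded by these orders. With 7 choices of the array set alone against the remaining 6, the 0 h array called 219 features and the highest other, the 12 h array, called 18. These choices are too few for a share under 0.05.

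The baseline array stood apart from the heated arrays. A fault unrelated to the other arrays would not make the 0 h array resemble what sets 2 h apart from 8 and 12 h. Over 13369 features the 0 h array, with no other array subtracted, correlated with the deviation of 2 h from the mean of 8 and 12 h at r = 0.352 (95% bootstrap interval over print blocks 0.332 to 0.372), against 0.029 for 4 h, -0.103 for 6 h and -0.332 for 10 h. The 4, 6 and 10 h arrays are heated and correlate with 8 and 12 h, so lower values were likely for them. The correlation of the 0 h array itself argues against a fault unrelated to the other arrays as the whole cause. A fault shared by the 0 and 2 h arrays stays open, and the interval does not cover differences between arrays. A drift in the order of processing, or 12 h more of age, would follow time as heating does and stays open, since there is no unheated time course here.

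Genes next to each other on a chromosome changed together over 0 to 12 h, with r = 0.202 across 1520 neighbouring pairs, which are not independent. The highest r in 1000 shuffles of gene order was 0.137 (one-sided permutation p = 0.001, the smallest they can give), which argues against chance order. Neighbours printed at the same row and column had r = 0.326 (95% interval 0.205 to 0.432). Pairs printed like these but far apart on the genome had r = 0.069 (0.0370 to 0.102), which argues against printing order as the whole cause. Neighbours printed at other rows or columns had r = 0.148 (95% interval 0.0910 to 0.204). The interval of the far pairs printed alike lies above 0, so a small share goes with print position. Pairs are not independent, and how large this share is among neighbours stays open. Both genes passed in 8 pairs, such as T16G1.6 with T16G1.7 and F46A8.3 with F46A8.4, where 4.4 would be expected of independent genes. This difference was not tested, and the pairs among F46A8.3, F46A8.4 and F46A8.5 share a gene. Shared regulation may contribute, and similar sequences of adjacent gene copies on the probes stay open without probe sequences.

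The carboxylesterase family had a median change of -1.01 over 0 to 12 h. It was -0.59 when the 0 h array was left out and the slope over 2 to 12 h was extended to 12 h. Offsets of print blocks are argued against by a median of -0.998 after centring each block. A single tandem cluster is argued against by the 10 members with no other protein-coding member within 2 genes. Their median of -0.84 lay at percentile 0.04 of 10000 random lists, with 1 of the 10 above 0. Random lists take genes as independent, so the percentile may be too extreme if members move together. A looser cluster, or one that includes family pseudogenes, was not looked at. Cross-hybridisation of one abundant transcript of the family cannot be told apart from a shared change, because the median correlation of member profiles, 0.32, sets no bound without the probe sequences. A fall of several members with heating or age may be followed up as a hypothesis found and tested on the same data.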
